A study of Mus musculus with 4 samples.

How the data were processed

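Quiescent muscle stem cells were freshly isolated from B6 mice, per the labels, and RNA was taken from Dek precipitates and from Input. Libraries of polyadenylated RNA were made with SMART-Seq v4 and tagmentation and were sequenced in pairs. Of the 4 libraries, 2 were Dek IP and 2 were Input, and the labels number the replicates 1 and 2 in each group. The labels do not say whether the replicates came from separate animals or isolations, so p-values measure only the spread between these samples, which may be technical. The sample labels name no precipitation with a control antibody, so RNA bound to Dek and RNA held by the precipitation itself cannot be separated.

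The deposited table holds FPKM values for 10847 genes, calculated by the authors, and per the submitters' processing notes the tools included HISAT2 2.1.0, SAMtools 1.9 and featureCounts of Subread 1.6.4 with the mm10 build. Which of these steps made the FPKM table is not stated in the sources used here. No cell of the table is 0, so each listed gene had fragments in all 4 libraries, and genes missed in any library cannot be read from it. The table's columns are named Ctrl_input and Ctrl_IP, and the labels do not say whether Ctrl stands for control animals or for a control precipitation. Columns were matched to samples by fraction and replicate number, and the IP columns were taken as Dek IP from the sample titles. If they held a control precipitation, the fold changes would not describe RNA recovered with Dek. A spreadsheet had turned 20 gene names into dates, and these rows were tested but not named. Of the names, 10366 matched a symbol and 437 a synonym in the RefSeq gene table of GRCm38.p6, and 44 matched neither. Positions were taken from that table, which uses the same build as mm10. Mitochondrially encoded genes are not in the table and were not analysed here.

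The FPKM values kept the depth of the libraries. Within each gene, values in the 4 libraries were related as whole numbers, and for single-exon genes the gene span then gave the total behind each library. The most common solution was given by 213 genes, and the next by 13. With the totals fixed, a gene length was found for 100% of genes at which all 4 values came out as whole fragments, within 0.0001 fragments. On 2991 simulated genes all 4 totals were recovered and 97.3% of genes had exact counts. For the rest the counts and the recovered length can be too low by a common factor. The totals were 62022430 and 44132716 for Input and 45034330 and 34640852 for Dek IP, of which 36.9%, 35.9%, 37.8% and 38.2% lay in the listed genes. Intervals for shares are 95% exact binomial (Clopper-Pearson) intervals; without molecular identifiers they cover counting error only. Recovered counts were used for depth, for tests of sampling noise, for gene length and in 1 alternative fit.

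Dek IP and Input were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with lmFit and eBayes with a variance trend, for the 7177 genes with a mean of at least 1 over the 4 libraries. The other 3670 were not tested. P-values were adjusted after Benjamini and Hochberg, and genes with an adjusted p under 0.05 are called enriched (higher in Dek IP, "rose") or depleted ("fell"). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Errors are SD between replicates or the SE of the fit. Each group had 2 libraries, so the spread came mostly from the shared prior (13.6 prior against 2 residual degrees of freedom). On simulated data with known changes the fit called 55% of genes changed 2-fold and 98% of genes changed 4-fold. Of the calls 6.13% were unchanged genes, and 0 calls had the wrong sign. The simulation took its variances from the fit's own prior, with independent genes, equal spread in both groups and no general shift. In these data the Input pair differed more than the Dek IP pair, so the simulation does not give the error rate of the calls.

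Gene lists for RNA classes, chromatin, splicing, stem cell state and other cell types were written before the data were examined, as were the design and the rule for named genes. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over 20 lists. The rule named Dek, the 12 genes with the largest enrichment and the 12 with the largest depletion among those with an adjusted p under 0.05, a mean of at least 5 in the higher group and no overlap between groups, leaving out names of the form Gm plus digits and names that end in Rik or in -ps plus digits. This left out 1 depleted gene and 0 enriched genes. It also named up to 3 members of each list by the smallest p, 4 quiescence genes and up to 2 abundant markers of each other cell type. Rn45s and Gpx3 were named after their values were seen, as were the further list members named where few passed. Reads of genes with near-identical copies, and of overlapping genes, may have been assigned wrongly, since the strand setting of the counting is not given in the sources used here.

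Alternatives were another pseudocount (0.1), other filters, centring, quantile normalization, equal sums, each library left out, no variance trend and the replicate number as a term. A voom fit of the recovered counts, equal sums without Rn45s and removal of the trend with gene length by loess were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.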

Results

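RNA that co-precipitated with the protein Dek was compared with input RNA from quiescent mouse muscle stem cells. Dek is a chromatin-associated nuclear protein that has been linked to splicing, and the title of the study places it in the control of intron retention and of exit from quiescence. Muscle stem cells, also called satellite cells, rest between the muscle fibre and its basal lamina until they are activated. The data were 4 libraries of polyadenylated RNA, 2 from Dek precipitates (Dek IP) per the sample titles and 2 from Input, listed as FPKM for 10847 genes. The table's own column names, Ctrl_IP and Ctrl_input, leave open whether a control precipitation is meant. FPKM is the number of fragments per kilobase of gene, scaled to the total of the library. The totals behind the values were worked out as 62022430 and 44132716 fragments for the Input libraries and 45034330 and 34640852 for the Dek IP libraries. A gene of median depth had 425 and 257 fragments in the Input libraries and 248 and 216 in the Dek IP libraries. The comparison asks which RNAs were over- or under-represented among those recovered with Dek.

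Across the 7177 tested genes, the Dek IP libraries were closer to each other than the Input libraries were. The Spearman correlation across genes was 0.982 between the Dek IP libraries and 0.933 between the Input libraries, and lay between 0.909 and 0.922 for pairs of an Input and a Dek IP library. Genes are not independent replicates, so these correlations only describe the libraries. Over the tested genes, the median absolute log2 difference was 0.18 between the Dek IP libraries and 0.27 between the Input libraries. Across the groups it was 0.33 to 0.44. Both replicate pairs differed by more than sampling noise: among genes with 500 to 2000 recovered fragments, the squared difference was 40.4 times the sampling noise for Input and 7.38 times for Dek IP. No pair therefore looked like a repeated deposit of 1 library, and all 4 were kept. Sampling noise covers counting error only, so this does not tell whether replicates were separate isolations or technical preparations.

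Dek RNA itself was higher in the Dek IP libraries, at 44.9 ± 6.21 FPKM (SD, n = 2) against 27.9 ± 1.43 in Input. The Dek gene lies on chromosome 13 from 47084767 to 47107530. Its log2 fold change was 0.66 ± 0.19 (SE), 1.58-fold on the log2(FPKM + 1) scale, with a limma adjusted p of 0.0448. The call is close to the threshold: it held in 8 of 15 alternatives, with adjusted p from 0.00894 to 0.227 and log2 fold changes from 0.53 to 0.93. It was lost without Input replicate 2 (log2 fold change 0.61), without Dek IP replicate 1 (0.80) and without Dek IP replicate 2 (0.53). It was also lost without a filter (limma adjusted p = 0.0975), without the variance trend (0.0861) and in voom (0.0516). The remaining loss was in the fit with the replicate number as a term, described with the dependence on processing.

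The 12 named genes with the largest enrichment included the transcription factors Cebpb, Mafg, Sox4 and Jund, the signalling genes Irs2 and Dusp5, and the genes Hnrnpab and Srrm2 for RNA-processing proteins, besides the rows Lars2 and Mir6236. The 12 with the largest depletion included Mir5133 and both ferritin subunits. Cebpb, a bZIP transcription factor, reached 28.0 ± 11.7 FPKM (SD, n = 2) in Dek IP against 5.15 ± 0.693 in Input, 4.53-fold on the log2(FPKM + 1) scale. Fth1 and Ftl1, the heavy and light chains of the iron store ferritin, were 3.16-fold and 2.93-fold lower in Dek IP on that scale. In all, limma called 202 genes enriched and 447 depleted at an adjusted p under 0.05, of which 69 and 95 differed at least 2-fold. The median log2 fold change of the tested genes was -0.18, and changes of single genes are to be read against that value. In 4266 genes (59.4%) the values of the groups did not overlap, against 33.3% for a single gene if the 4 libraries were interchangeable. All genes share these libraries, so a library-wide difference can raise this share, and the excess is no evidence for single genes. At least 2-fold differences between every Dek IP and every Input library were found for 18 genes that were higher and 24 that were lower in Dek IP. That balance turned with scaling, to 46 and 8 after centring on the median, 44 and 10 after quantile normalization and 36 and 12 with equal sums without the row Rn45s.

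The split between enriched and depleted calls depended on scaling: 31.1% of calls were enriched as deposited, 58.1% after centring on the median of the tested genes (415 against 299), 67.3% after quantile normalization (387 against 188) and 49.2% after scaling to the same sum without the rRNA precursor row Rn45s (306 against 316). Without a filter on low values limma called 0 genes, with 2474 of 10847 at an unadjusted p under 0.05, and leaving out 1 library gave 796 enriched and 982 depleted genes without Input replicate 1, 489 and 1714 without Input replicate 2, 48 and 51 without Dek IP replicate 1, and 53 and 219 without Dek IP replicate 2. A smaller set of 154 enriched and 137 depleted genes kept its call with another pseudocount, in 4 other scalings and in a count-based voom fit. These 6 alternatives include neither the change of filter nor the left-out libraries, so a call kept in them can still be lost there.

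**Figure D1:**
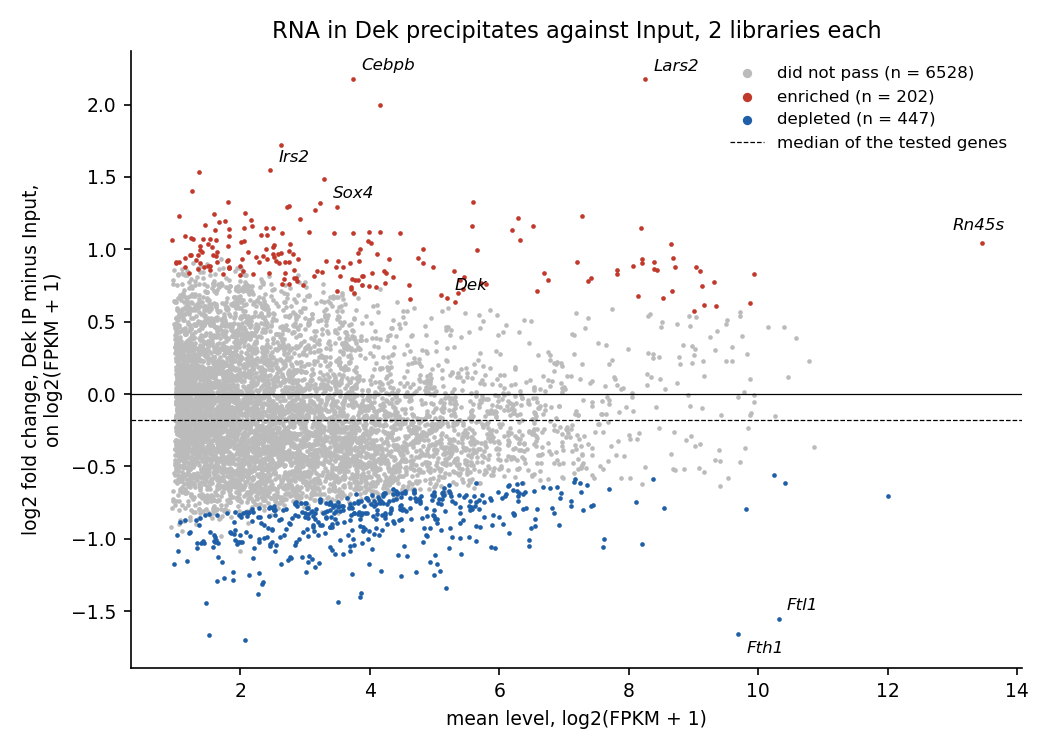
Log2 fold change of Dek IP over Input on the log2(FPKM + 1) scale (vertical axis) against mean level in log2(FPKM + 1) (horizontal axis), 1 point per tested gene. Red points are the 202 enriched and blue points the 447 depleted genes, and the dashed line marks the median of -0.18; Cebpb and Lars2 lie highest, and Fth1 and Ftl1 lie low among the most abundant genes.

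Among the 12 named enriched genes, 4 encode DNA-binding transcription factors. Besides Cebpb (log2 fold change 2.18 ± 0.26 SE, limma adjusted p = 0.000775; chromosome 2, 167688915 to 167690432), these were the small Maf protein Mafg (1.72 ± 0.26), the SRY-box factor Sox4 (1.49 ± 0.21) and the AP-1 subunit Jund (1.29 ± 0.24). The signalling genes were Irs2, an adaptor of the insulin receptor (1.55 ± 0.24), and Dusp5, a nuclear phosphatase of ERK (1.32 ± 0.25). Transcripts of the RNA-binding protein Hnrnpab rose from 29.4 ± 3.89 to 75.2 ± 3.09 FPKM (SD, n = 2; log2 fold change 1.33 ± 0.19). Srrm2, a scaffold protein of nuclear speckles, rose by 1.30 ± 0.26 on the log2 scale. The mitochondrial kinase Pink1 (1.29 ± 0.21) and the proprotein convertase Furin (1.27 ± 0.25) were enriched to about the same degree. Rows for Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, and for Mir6236 stood at 648.4 and 35.7 FPKM in Dek IP against 142.6 and 7.68 in Input. Their levels moved with that of the rRNA precursor row Rn45s, described with the library shares. Adjusted p of the 12 genes in limma ran from 9.59e-05 for Lars2 to 0.0121 for Srrm2, and all 12 kept their call in the 6 alternatives of pseudocount, scaling and voom.

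Of the named genes, Mir5133 had the largest depletion (log2 fold change -1.70 ± 0.29), followed by both ferritin genes. The Mir5133 row is only 77 bases long, at 4.40 and 9.12 FPKM in Input and 1.44 and 1.12 in Dek IP. Its values therefore rest on few fragments. Fth1 (chromosome 19, 9980600 to 9985111) fell from 1459 ± 103 to 461.4 ± 46.6 FPKM (SD, n = 2; log2 fold change -1.66 ± 0.17 SE, limma adjusted p = 0.000169). Ftl1 (chromosome 7, 45457944 to 45459886) fell from 2160 ± 7.64 to 748.1 ± 190 FPKM (log2 fold change -1.55 ± 0.19, limma adjusted p = 0.000806). Both ferritin genes have processed pseudogenes, so the assignment of their reads carries some uncertainty. Bola3, a factor for iron-sulfur cluster assembly in mitochondria, had a log2 fold change of -1.43 ± 0.22. The endoplasmic reticulum protein Tmem147 (-1.40 ± 0.24), the plasma membrane protein Ninj1 (-1.38 ± 0.20) and the carnitine transporter Slc22a5 (-1.30 ± 0.28) were also depleted, as was Tm2d1 (-1.26 ± 0.20). Bag2, a co-chaperone of Hsp70, fell with a log2 fold change of -1.38 ± 0.24, and Brms1l, a subunit of a histone deacetylase complex, with -1.31 ± 0.25. The remaining genes were Tma7 (-1.25 ± 0.19) and the interferon-inducible GTPase Ifi47 (-1.25 ± 0.24). Adjusted p in limma ran from 0.000169 to 0.0136 over these 12 genes, and 11 kept their call in the same 6 alternatives. The call for Mir5133 was lost in voom (adjusted p = 0.0985).

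**Figure D2:**
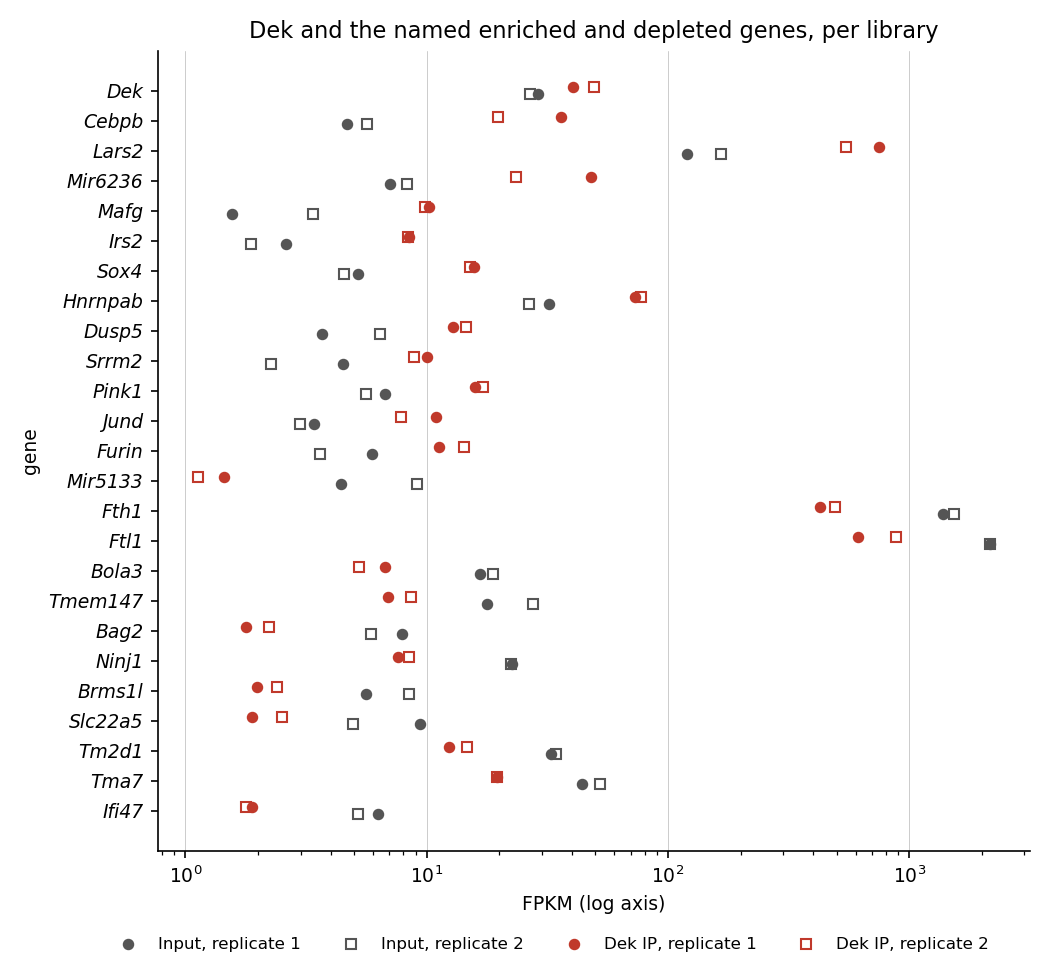
FPKM on a log axis (horizontal) of Dek, the 12 named enriched genes and the 12 named depleted genes (vertical), 1 symbol per library: grey for Input, red for Dek IP, filled circles for replicate 1 and open squares for replicate 2. In every gene shown both red symbols lie on the same side of both grey symbols, which the naming rule required of all genes but Dek. For Fth1 the red symbols lie at 428.5 and 494.3 FPKM and the grey ones at 1386 and 1531.

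Fixed gene lists were used to ask whether whole classes of RNA were recovered with Dek. Transcripts of cytosolic ribosomal proteins (median log2 fold change 0.48) and of chromatin remodellers and histone modifiers (0.37) lay above other genes, with -0.18 as the median of all tested genes. Those of hnRNP proteins (0.07) and of SR proteins and splicing kinases (-0.04) were also placed above other genes, with medians near 0, and proteasome subunits (-0.31) below them. With limma's camera at a preset correlation of 0.01, 6 of 20 lists were higher and 1 was lower at an adjusted p under 0.05. With an estimated correlation between genes 0 lists passed, and 0 passed in the directional test of fry. The list calls therefore describe a position relative to other genes that rests on the preset value. Both other tests rest on the 2 residual degrees of freedom, so they had little power and cannot argue against a shift. In the mixed test of fry, which asks whether members change in either direction, 11 lists passed.

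Ribosomal protein genes formed the largest group: 29 of 78 tested members rose and 1 fell, or 43 and 1 adjusted over the list alone. Their median log2 fold change was 0.48 (limma camera adjusted p = 2.0e-26; adjusted p = 0.817 with an estimated correlation), and 75 of the 78 lay above the median of all tested genes. Rps10 stood at 429.6 ± 4.85 FPKM (SD, n = 2) in Dek IP against 194.6 ± 26.0 in Input. Rps21 (2.34-fold) and Rplp2 (2.05-fold) rose by similar amounts. The member that fell was Rplp0, a stalk protein of the large subunit (log2 fold change -0.61 ± 0.18), whose call was lost in at least 1 of the 6 alternatives; 24 of the 29 risen members kept theirs in all of them. Many of these genes have processed pseudogenes, which adds uncertainty to single values. In the same libraries the row Rn45s, named for the precursor of ribosomal RNA, was also higher in Dek IP. Its call was lost after centring and with equal sums. Whether its reads came from the precursor or from mature ribosomal RNA was not analysed here.

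Genes of chromatin regulation rose in 8 of 36 tested cases, or 11 adjusted over the list alone. The list was higher than other genes (limma camera adjusted p = 2.2e-08; adjusted p = 0.817 with an estimated correlation). Its median log2 fold change was 0.37, which fell to -0.07 without the trend with gene length, against -0.23 for all genes, with a camera adjusted p of 0.0138. Brd4, a reader of acetylated histones, rose 2.17-fold from 4.68 ± 0.490 to 11.3 ± 0.808 FPKM (SD, n = 2). Crebbp, a histone acetyltransferase, and Kdm6b, a demethylase of histone H3, rose 2.21-fold and 1.92-fold. The remodelling ATPases Smarca5 and Chd4, Hdac4 and Bptf also rose, and the last of the 8 was Dek itself. Apart from Dek, each kept its call in the 6 alternatives.

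RNAs for splicing regulators were split. Of 30 SR proteins and splicing kinases 5 rose and 1 fell, or 8 and 1 adjusted over the list alone. Their median log2 fold change was -0.04, or 0.11 after centring, whereas the mean was 0.12 and camera placed the list higher than other genes (limma adjusted p = 0.0201; adjusted p = 0.817 with an estimated correlation). Srsf2 rose from 50.1 ± 1.62 to 117.8 ± 1.59 FPKM (SD, n = 2), and Srsf1 from 10.1 ± 0.371 to 18.6 ± 0.0122. The speckle proteins Srrm1, Srrm2 and Son rose as well, and Srsf10 fell (log2 fold change -0.68 ± 0.20). Of 26 hnRNP proteins 4 rose, or 6 with 1 fall adjusted over the list alone, with a median log2 fold change of 0.07 (limma camera adjusted p = 0.000462; adjusted p = 0.817 with an estimated correlation). Besides Hnrnpab these were Hnrnpa0 (2.32-fold), Pcbp1 (2.09-fold) and Hnrnpu. The core spliceosome did not pass as a list (median log2 fold change -0.19, or 0.08 after quantile normalization, limma camera adjusted p = 0.829), and of its 48 tested members 1 fell, the Sm-like protein Lsm5, both over all genes and adjusted over the list alone. The calls for Srsf10, Hnrnpu and Lsm5 were each lost in at least 1 of the 6 alternatives.

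Genes of nuclear export and RNA surveillance were slightly higher as a list (30 tested, median log2 fold change 0.11, limma camera adjusted p = 0.0323; adjusted p = 0.817 with an estimated correlation). Alyref, an mRNA export adaptor, rose 1.96-fold and was the only member to pass over all genes or adjusted over the list alone, but its call was lost in at least 1 of the 6 alternatives. Very long genes of the matrix and cytoskeleton had a median of 0.25 (17 tested, limma camera adjusted p = 0.0135; adjusted p = 0.817 with an estimated correlation), where Hspg2 rose and Col6a1 fell, with 2 and 1 adjusted over the list alone. The 31 proteasome genes had a median of -0.31 (limma camera adjusted p = 0.0135; adjusted p = 0.891 with an estimated correlation), and Psmd8, Psmb2 and Psma3 fell between 1.56-fold and 1.63-fold, 3 also adjusted over the list alone. In all 6 alternatives Hspg2 and Psmb2 kept their calls, and Col6a1, Psmd8 and Psma3 did not. The proteasome list lost its call in quantile-normalized values (camera adjusted p = 0.439), and after removal of the trend with gene length the export, very long and proteasome lists all lost theirs (camera adjusted p = 0.0602, 0.738 and 0.243).

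**Figure D3:**
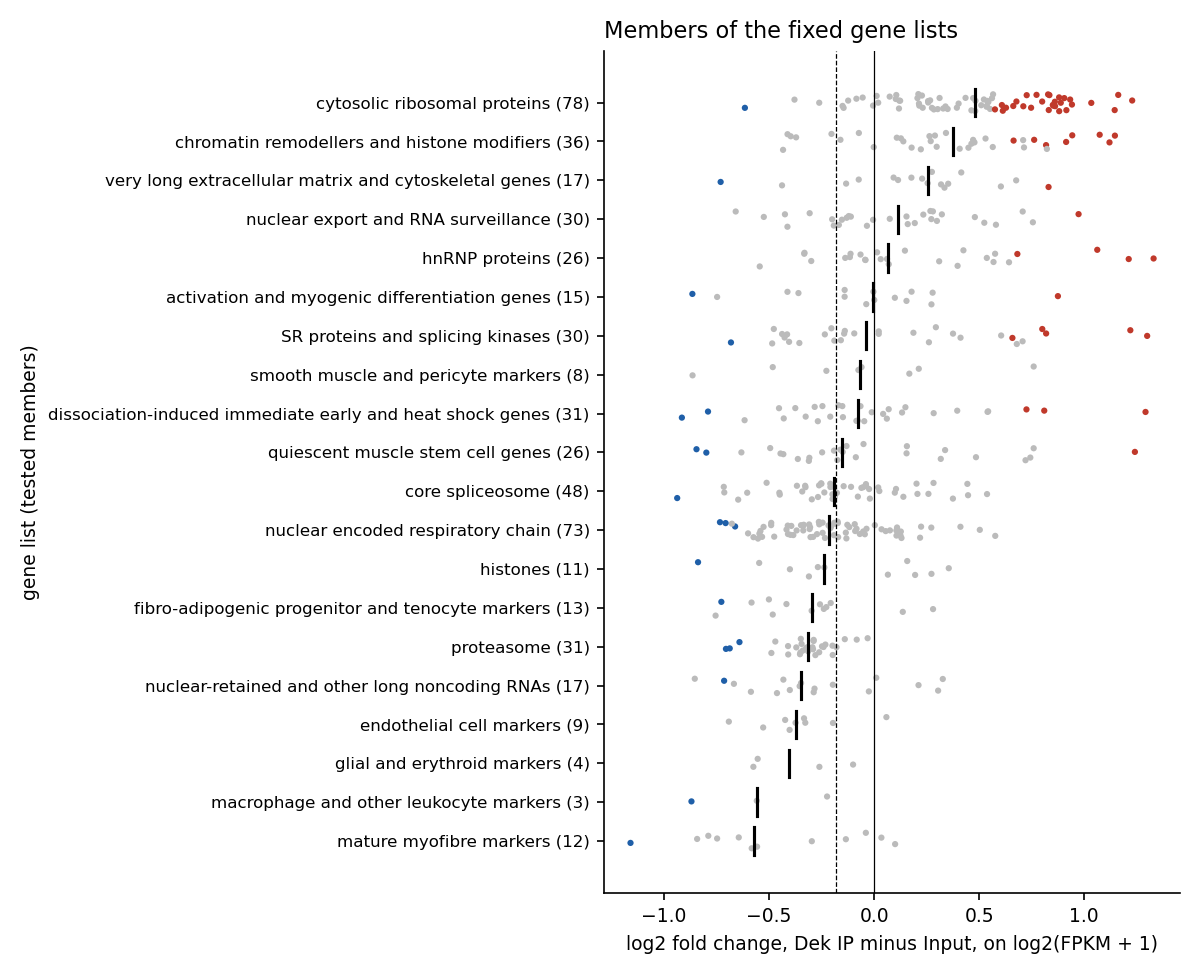
Log2 fold change of Dek IP over Input on the log2(FPKM + 1) scale (horizontal axis) for the tested members of each fixed list with 3 or more (vertical axis, number tested in parentheses), red for enriched, blue for depleted and grey for genes that did not pass. Black bars are list medians and the dashed line is the median of all tested genes, -0.18; ribosomal protein genes have the highest median, 0.48.

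Markers of quiescent muscle stem cells did not move together. Of 26 tested genes 1 rose and 2 fell, or 3 and 3 adjusted over the list alone (limma camera adjusted p = 0.597). The cell cycle inhibitor Cdkn1c rose from 0.959 ± 0.393 to 3.65 ± 1.14 FPKM (SD, n = 2). The surface proteins Vcam1 and Cd34 fell 1.74-fold and 1.80-fold, and of these 3 genes Cd34 alone lost its call in at least 1 of the 6 alternatives. Pax7, the transcription factor that marks these cells, stood at 1.43 ± 0.0268 in Dek IP and 0.927 ± 0.180 FPKM in Input (limma adjusted p = 0.381). Spry1 (19.3 and 20.6 against 22.8 and 22.4 FPKM) and Calcr (5.51 against 9.09) did not pass either. In the list of activation and differentiation genes the cyclin Ccnd1 rose (1.83-fold) and the nucleolar protein Nop56 fell (1.82-fold) among 15, likewise 1 and 1 adjusted over the list alone (camera adjusted p = 0.480). The creatine kinase gene Ckm was at 1.61 ± 0.105 against 3.78 ± 2.74 FPKM. Of 31 immediate early and heat shock genes, which dissociation of tissue can induce, Jund, Klf4 and Ier5 rose and Dnajb1 and Dusp1 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.328). Of these 5 genes Dnajb1 did not keep its call in all 6 alternatives.

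Other RNA classes showed few calls. Of 73 nuclear-encoded respiratory chain genes 3 fell, Atp5g1, Ndufb9 and Ndufb8 (0 adjusted over the list alone, and 14 lower and 3 higher at an unadjusted p under 0.05; limma camera adjusted p = 0.256), and none of the 3 kept its call in all 6 alternatives. Of 17 long noncoding RNAs Snhg3 fell, or 2 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.328), and the nuclear RNAs Neat1 and Pvt1 did not pass over all genes (limma adjusted p = 0.0531 and 0.0699). Histone genes had 1 depleted member of 11, the linker histone H1f0 (camera adjusted p = 0.829; 1 adjusted over the list alone). A single structured small RNA, Rnu12, was tested, at 1.35 ± 1.08 against 2.84 ± 0.678 FPKM (limma adjusted p = 0.111; fell adjusted over the list alone, where it is 1 test). The calls for Snhg3 and H1f0 were each lost in at least 1 of the 6 alternatives.

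Markers of other cell types can be read only where the table lists them, which it does for genes with fragments in all 4 libraries. Of 16 leukocyte markers 11 were listed, and of 11 glial and erythroid markers 5. For mature muscle fibres, Acta1 was at 17.6 FPKM in Input replicate 1, 6.51 in Input replicate 2, and 9.26 and 5.27 in the Dek IP libraries, so that Input replicate 1 stood apart. In that list Atp2a1, the calcium pump of fast fibres, was 1 of 12 genes to fall (list median log2 fold change -0.57, limma camera adjusted p = 0.233; 1 adjusted over the list alone). The fibroblast and tendon list had a median of -0.30 (13 tested, camera adjusted p = 0.211), with Tnmd the member to fall, or 3 adjusted over the list alone, and with Dcn at 102.3 ± 11.3 against 154.2 ± 23.5 FPKM. Among 3 leukocyte genes Cd74 fell, or 2 adjusted over the list alone, with Lyz2 at 5.32 against 8.28 FPKM (camera adjusted p = 0.256). Of 9 endothelial genes 0 were called by limma at either adjustment, with 3 lower at an unadjusted p under 0.05, and Fabp4 was at 26.3 against 35.6 FPKM (camera adjusted p = 0.256). The 8 smooth muscle and pericyte genes had 0 limma calls over all genes, with 1 higher and 2 lower at an unadjusted p under 0.05, or 1 rise and 1 fall adjusted over the list alone (camera adjusted p = 0.717). The 4 glial and erythroid genes had 0 calls in limma at either adjustment, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.577). Of the markers called over all genes, Atp2a1 kept its call in all 6 alternatives, and Tnmd and Cd74 did not.

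The make-up of the libraries also differed. Rn45s took 10.2% and 7.10% of the summed FPKM in the Dek IP libraries against 3.01% and 5.27% in Input. As recovered fragments, its share of the total was 10.6% (95% exact interval 10.57 to 10.59) and 7.97% (7.96 to 7.98) in Dek IP, and 3.43% (3.43 to 3.44) and 5.76% (5.75 to 5.77) in Input. These intervals cover counting error only, and the difference between the replicates was much wider. Rn45s rose 2.07-fold (limma adjusted p = 0.0143), with a log2 fold change of 1.05. The call was lost after centring on the median (log2 fold change 1.19, limma adjusted p = 0.0646), with equal sums (1.10, adjusted p = 0.0514) and with equal sums without Rn45s (1.17, adjusted p = 0.0588). It was also lost without Dek IP replicate 1 (0.84, adjusted p = 0.175), without the variance trend (adjusted p = 0.0521) and without a filter (0.132). Quantile normalization gives rows of the same rank in every library the same value, and so cannot test Rn45s or Gpx3, the first and second row of each library. Ribosomal protein genes held 23.2% and 23.5% of summed FPKM in Dek IP and 16.2% and 18.8% in Input. The ferritins Fth1 and Ftl1 together held 0.587% and 0.716% against 1.82% and 1.97%. Gpx3, a secreted glutathione peroxidase, held 1.61% and 1.88% against 2.90% and 2.59%, and its fall (limma adjusted p = 0.0280) was lost after centring (log2 fold change -0.56 in place of -0.71, adjusted p = 0.0994) and with equal sums without Rn45s (-0.59, adjusted p = 0.0600). It was also lost without Dek IP replicate 1 (-0.54, adjusted p = 0.418), without Dek IP replicate 2 (-0.88, adjusted p = 0.0623), without the variance trend (adjusted p = 0.0796) and without a filter (0.148). Nuclear-encoded respiratory chain genes held 2.39% and 2.69% against 2.71% and 2.77%. With 2 libraries per group an exact test of such shares cannot go below p = 0.333, so none was run.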

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

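All alternatives were fixed before the data were examined except voom, equal sums without Rn45s and removal of the length trend. Over 15 settings, 1482 of 1772 values of named genes and lists kept their side of the threshold, 213 lost a call, 76 gained one and 1 called result reversed in its own test (camera for lists; changes of sign of uncalled values and of list medians are not counted). This was the list of very long matrix and cytoskeletal genes, whose direction in camera turned downward without the length trend, but not as a call (adjusted p = 0.738). Its median log2 fold change of -0.19 there lay near the -0.23 of all genes, since that setting removes what long genes share. The medians of the chromatin and nuclear export lists fell to -0.07 there, still above that of all genes. Their direction in camera stayed upward (adjusted p = 0.0138 and 0.0602). The 202 enriched and 447 depleted genes became 191 and 422 with a pseudocount of 0.1, 0 and 0 without a filter (2474 at an unadjusted p under 0.05 in limma), 207 and 725 with a mean of at least 5, 415 and 299 after centring on the median, 387 and 188 after quantile normalization, 239 and 410 with equal sums, 306 and 316 with equal sums without Rn45s, 116 and 168 without the variance trend, 212 and 281 in voom, 165 and 541 without the length trend, and 69 and 95 with a 2-fold minimum. Scaling moved the median log2 fold change of all genes from -0.18 to -0.04 (centring, quantile) or -0.08 (equal sums without Rn45s); centring raises all genes by about the same amount by construction. Leaving out each library in turn gave 48 to 796 enriched and 51 to 1714 depleted genes; there the lone library is assumed to vary like the other group. The closer Dek IP pair then sets the spread when an Input library is left out, and the Input pair when a Dek IP library is.

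Genes at least 2-fold apart in every pair of libraries (18 higher, 24 lower) numbered 72 and 79 with a pseudocount of 0.1, 13 and 15 with a mean of at least 5, 46 and 8 after centring, 44 and 10 after quantile normalization, 36 and 12 with equal sums without Rn45s, and 26 to 127 higher and 39 to 134 lower with each library left out. The 6 higher lists and 1 lower list became 4 and 0 with a mean of at least 5, 6 and 0 after quantile normalization, 4 and 0 without the length trend, 3 to 5 and 0 to 2 with each library left out, and 0 and 0 with an estimated correlation or in the directional test of fry (11 lists passed its mixed test, which has no direction). Where no reason is given, the cause was not tested.

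With the replicate block 197 genes were enriched and 375 depleted, of which 182 and 354 were also called without it, and Dek was not called (adjusted p = 0.0629, log2 fold change 0.66 as without the block); deviations of same-numbered libraries correlated at 0.129 over genes, but with 2 pairs the numbers were not taken to pair the samples. The other 2 ways to split the 4 libraries 2 by 2 gave 0 limma calls each (73 and 57 genes at an unadjusted p under 0.05) against 649. Both put a Dek IP and an Input library in each group, so the difference between fractions enters the residual spread. Few calls then follow whatever caused that difference, so these splits are no test of the 649 calls. Also, 3 splits cannot give a share under 0.05. The planned negative binomial test of recovered counts was not run and voom took its place; shares without mitochondrially encoded genes could not be computed since the table has none. Depth limits genes of few fragments: between 341 and 583 genes per library had under 10.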

Other observations

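The tests of ribosomal RNA rows, of single-exon genes, of counting error, of the pseudocount and of abundant genes without ribosomal protein genes below, and the choice of gene families and RNA classes, were made after the results they concern were seen. Genes were grouped by the letters of their symbol before the first digit, which gave 39 families of at least 15 tested genes. In limma's camera 0 families passed with an estimated correlation, which has little power at 2 residual degrees of freedom. At the preset correlation 3 passed. Besides the Rpl and Rps genes, this was the Tmem family of membrane proteins, with 15 of 96 members depleted and a median log2 fold change of -0.37 (camera adjusted p = 0.00438; adjusted p = 0.992 with an estimated correlation). The median of Tmem genes stayed between -0.33 and -0.22 in the 4 other scalings. Only 0.05% of 10000 random lists matched on length and level had a median as low. Such lists, here and below, draw genes from the same 4 libraries as if independent. Their percentiles give a position among genes, not the spread between replicates. The call of the Tmem family held without the trend with gene length (camera adjusted p = 0.0263). Solute carriers of the Slc family had 12 depleted and 1 enriched of 110 genes and a median of -0.31, as low as 0.07% of matched lists, but did not pass in camera (adjusted p = 0.259).

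Long noncoding RNAs as annotated, a wider class than the fixed list, had 9 depleted genes of 73 and a median log2 fold change of -0.35 (-0.33 to -0.21 in the other scalings), as low as 0.42% of matched lists, with a camera adjusted p of 0.0277 over 4 classes (0.416 with an estimated correlation, so the call rests on the preset value). Transcribed pseudogenes had a median of 0.14 over 15 genes with 1 depleted; this lay at the 99.85th percentile of matched lists, while camera gave an adjusted p of 0.139. Rows for snoRNAs and miRNAs, which mostly lie in introns of other genes, went both ways: 3 of 38 were enriched and 7 depleted, with a median of -0.38, as low as 2.92% of matched lists (camera adjusted p = 0.215).

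The rows of Rn45s, Lars2 and Mir6236 were all higher with Dek. Lars2 had 27.5 and 26.7 recovered fragments per 1000 of Rn45s in Dek IP but 13.5 and 11.2 in Input. That is a ratio of 2.19, where replicates differed by at most 1.21. These values argue against a source that gives reads to Rn45s and Lars2 in a fixed proportion. If the proportion can differ between the fractions, a shared source stays open. For Mir6236 and Lars2 the fragment ratio in Dek IP was 0.979 times that of Input, within the 1.49 between replicates. This cannot show a shared source: both rows were singled out for large enrichment, and rows enriched alike give such a ratio. Mir6236 also had only 45 to 266 fragments per library. Reads of ribosomal origin assigned to Lars2 and Mir6236 are a candidate explanation. It could be checked by where in the rows the reads lie, which was not analysed here. Whether Dek binds these RNAs, or the precipitation holds them, stays open without a control precipitation.

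Longer genes were higher in Dek IP: the Spearman correlation of log2 fold change and recovered exonic length was 0.299 across 7177 genes, which are not independent, and 0.216 to 0.301 in each pair of a Dek IP and an Input library, against 0.147 between the Dek IP replicates and 0.0698 between the Input replicates. Counting error is argued against as the cause, since the correlation was 0.262 among 2508 genes with a mean of at least 1000 recovered fragments, and so is the pseudocount, with 0.283 without one. The trend may be carried by genes of low level, since it was -0.085 among the 1254 genes with a mean FPKM of at least 20, and 0.0125 among 1179 of them without the ribosomal protein genes (0.326 without these at all levels). Removing the trend left the call of the ribosomal protein list (camera adjusted p = 2.9e-40, median from 0.48 to 0.50). Less clearly, it left that of the chromatin list (camera adjusted p = 0.0138, median from 0.37 to -0.07). The median of all genes went from -0.18 to -0.23. Both calls used the preset correlation, and with an estimated one neither list passed before the removal (camera adjusted p = 0.817). The very long genes lost their call (camera adjusted p = 0.738), with quartiles going from 0.09 and 0.35 to -0.42 and -0.13. That list was chosen for length, so removing a trend with length takes away its shift whatever the cause. Differences in RNA fragmentation or capture between the fractions, and binding that increases with length, were not tested and stay open. So does a dependence on level that goes along with length, since no correlation with length at a given level was calculated.

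Protein-coding genes whose recovered length equalled their gene span were taken as single-exon, among them Cebpb, Jund, Hnrnpa0 and Zbed6. All others with a span were taken as spliced, so that class can also hold intronless genes whose annotated ends differ from the recovered length. Genes taken as single-exon were enriched in 7 of 71 cases against 186 of 6669 taken as spliced (9.86% and 2.79%). Fisher's exact test gave a two-sided p of 0.00400 over genes that are not independent. The median log2 fold change was -0.002 for genes taken as single-exon against -0.18 for those taken as spliced. The single-exon class may be recovered more with Dek at the same length and level. Its median stood at the 99.98th percentile of 10000 matched lists, with a camera adjusted p of 0.0145, but 0.502 with an estimated correlation. Genomic DNA in the precipitates was not tested and stays open. As a hypothesis, RNA without splice junctions may be favoured in Dek precipitates. The class taken as spliced is mixed, so the contrast cannot decide this. Intron reads, which would test the hypothesis for spliced genes, were not analysed here.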
